A study of Homo sapiens with 16 samples.

How the data were processed

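RNA sequencing profiles of 16 libraries were analysed, 8 from lymphatic endothelial cells (LEC) and 8 from macrophages. Within each cell type the sample titles mark 4 libraries as VEGFR3 and 4 as untreated. Those marked VEGFR3 were taken as treated with anti-VEGFR3, which the titles do not spell out. The titles also do not say whether cells or animals were treated. The labels give polyA RNA as the molecule and describe column-based isolation of total RNA with a requirement for high RNA integrity. The labels do not say whether the libraries came from separate animals, donors or cultures, so p-values measure the spread between these libraries, which may be technical.

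Each library has a file of whole-number read counts per gene that the authors deposited without normalization, per the file layout, which is the one STAR writes when it counts reads over genes. The file holds 4 summary lines (unmapped reads, reads at several positions, reads in no gene, reads overlapping several genes) and 46983 genes with 3 count columns, one that ignores strand and one for each strand. Per the submitters' processing notes, Trimmomatic, STAR, featureCounts and DESeq2 were used and the builds were GRCh38 and hg38; the versions and the annotation are not given in the sources used here. The organism in the labels is human. The identifiers of all 46983 genes carry ENSMUSG, the prefix Ensembl uses for mouse genes, and 0 of them matched the human gene name table or the RefSeq gene table supplied as references. The label and the identifiers therefore disagree. In every LEC library 81.4% to 84.8% of reads were assigned to 1 gene with the mouse prefix, which argues against human as the source of the LEC reads. Reads were not aligned to both genomes here, so the organism was not tested. The files do not pair identifiers with gene names, so genes are given by identifier alone, without name or position.

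The summary lines stayed out of library sizes and tests. Reads assigned to 1 gene made up 81.4% to 84.8% of the reads in LEC libraries and 22.8% to 78.3% in macrophage libraries. Both strand columns held about equal shares in every library (49.8% to 50.8% in the column of the first strand), so the column that ignores strand was used throughout, by a rule set before the data were examined. That column leaves out reads overlapping several genes and cannot separate a gene from an antisense partner, so values of overlapping genes are uncertain. The total of gene counts per library ran from 24684764 to 34349753 in LEC and from 5296562 to 22398944 in macrophages. A gene with 0 counts in 1 library could still lie at up to 3 counts, which on the scaled library sizes corresponds to 0.0838 to 0.127 CPM in the LEC treatment comparison 0.0926 to 1.12 CPM in that of macrophages and up to 1.49 CPM in fits of both cell types, where CPM are counts scaled to a common library total. Reads carry no molecular identifiers, so such limits and counting intervals cover counting error only.

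Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, on counts scaled by the trimmed mean of M values (TMM) after filterByExpr. Benjamini-Hochberg (BH) adjusted p-values under 0.05 were called. For the comparison of cell types a call also needed an absolute log2 fold change of at least 1. The comparisons were anti-VEGFR3 against untreated in the 8 LEC libraries, the same in the 8 macrophage libraries, LEC against macrophages in the 8 untreated libraries, and the difference of the treatment effects in one fit of all 16 libraries. Standard errors (SE) and 95% intervals of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values are scaled by TMM within each comparison and given as mean ± SD over 4 libraries. Single values per library were compared with exact two-sided permutation tests over all assignments of 8 libraries, for which 0.0286 is the smallest p.

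The design, these tests and most alternatives were fixed before the data were examined. They included 41 gene lists and a rule that named genes by symbol: the genes with the largest fold changes among those past the threshold with groups that did not overlap. As 0 identifiers matched a symbol, none of the 41 lists could be tested and the rule could not be applied. In its place 2 identifiers per direction were taken in each comparison, those with the smallest p and a mean of at least 1 CPM in the higher group. This replacement was set after the identifiers had been seen.

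Alternatives were the size factors of DESeq2 used in edgeR, DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights), no filter on low counts, a filter of at least 10 counts in at least 4 libraries, one strand column, replicate number as a block, blocks taken from the sample codes, one fit of all 16 libraries, and leaving out each library in turn. Added after the data were seen were the sum of both strand columns, fits on part of the sample codes, comparisons between sample codes, limits and recovery in the blocked macrophage fit, and scores of cell-cycle marker pairs from the mouse list shipped with scran 1.30.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

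Each label holds a code with a number from 1 to 4 after the letter G and another number after the letter M, whose meanings are not stated. Without its last letter, 7 of the 8 codes of each cell type were shared between LEC and macrophage libraries, among them all 4 of the untreated ones, and whether a shared code marks a shared source is not stated. By the G number, untreated libraries carry 1 or 2 and treated libraries 3 or 4. Replicates 1 and 2 of every group carry 1 or 3, and replicates 3 and 4 carry 2 or 4, so replicate number and code overlap. Whether replicate numbers pair treated with untreated libraries was checked from the correlation, across genes, of deviations from the group means. In macrophages the correlations of same-numbered libraries were 0.624, 0.507, 0.261 and 0.254, all above the limit of 0.1 set beforehand, and the numbers were taken to pair the libraries on that evidence alone. Replicates 1 and 4 correlated best with their own number, while replicates 2 and 3 correlated more with another (0.534 and 0.294). Same-numbered libraries also share a code set, so a difference between code sets alone could give such correlations. The check cannot tell pairing from a shared code set, and results that use the pairs rest on an unproven pairing. In LEC the correlations of same-numbered libraries were 0.135, -0.0085, 0.267 and 0.155, and the numbers were not taken to pair the libraries. No 2 libraries of a group differed by as little as sampling noise: over genes with at least 50 counts, the smallest mean squared difference in any pair of a cell type was 21.9 times that of sampling noise.

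The procedure was tested on simulated data. Counts were drawn for the real genes from the means and library sizes of the real libraries, with 200 genes changed, 100 by 2-fold and 100 by 4-fold. The changed genes of every simulation came from those with a mean of at least 1 CPM, so the shares do not describe recovery of genes below it. In the LEC treatment comparison 21% of 2-fold and 58% of 4-fold changes were recovered. The shares were 0% and 17% in the macrophage treatment comparison without a block, 3% and 64% in the comparison of cell types, and 1% and 24% for the difference of treatment effects. For the added comparisons between codes they were 28% and 71% in LEC and 13% and 72% in macrophages. Of the unchanged genes 0, 0, 3, 3, 2 and 6 were called, in the same order. In these simulations each gene had 1 mean over all libraries of a comparison before the changes. Recovery was scored by adjusted p alone, also for the cell types, without their limit on fold change. The real comparison of cell types called 6443 genes, far more than the 200 changed here, so its simulated shares do not describe recovery in the real data. With the replicate block in the macrophage fit and replicate effects kept in the simulated means, 13% of 2-fold and 65% of 4-fold changes were recovered and 5 unchanged genes were called.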

Results

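Gene expression was measured by RNA sequencing in lymphatic endothelial cells (LEC), which line lymphatic vessels, and in macrophages, phagocytic cells of the innate immune system. Each type was profiled in libraries titled untreated and in libraries titled VEGFR3, taken as treated with anti-VEGFR3, with 4 per group and 16 in all. VEGFR3 is the receptor tyrosine kinase through which VEGF-C and VEGF-D act on lymphatic endothelium. Per its title, the series concerns how VEGF-C signalling through VEGFR3 in lymphatic vessels and macrophages of colorectal tumours bears on immune escape. The labels do not state the source of the cells, or the dose or duration of the treatment.

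LEC libraries held 24684764 to 34349753 gene counts. Macrophage libraries fell into separate ranges by sample code. The 4 libraries coded 1 or 3 held 15588304 to 22398944 gene counts, and the 4 coded 2 or 4 held 5296562 to 9174379. Unmapped reads made up 5.23% to 6.79% of reads in LEC, 2.35% to 5.71% in macrophage libraries coded 1 or 3, and 21.01% to 49.6% in those coded 2 or 4. The 10 most abundant genes took 47.4% ± 10.3 (SD, n = 4) of gene counts in macrophage libraries coded 2 or 4 and 8.34% ± 1.94 (SD, n = 4) in those coded 1 or 3 (exact permutation test, two-sided p = 0.0286, the smallest possible; BH-adjusted p = 0.114 over 12 such tests). The gene with the highest mean share in macrophage libraries coded 2 or 4 was ENSMUSG00000106106.2, singled out after its values were seen. It took 19.4% ± 6.88 of counts there, 1.15% ± 0.471 in those coded 1 or 3 and 0.0067% ± 0.0030 in LEC (SD, with n = 4, 4 and 8). It was not alone. ENSMUSG00000076258.1 took 12.4% ± 5.57 in macrophage libraries coded 2 or 4 and 0.384% ± 0.166 in those coded 1 or 3. For ENSMUSG00000035202.7 the shares were 8.92% ± 3.78 and 0.911% ± 0.452. Each code set holds 2 treated and 2 untreated libraries, so it does not coincide with the treatment.

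**Figure D1:**
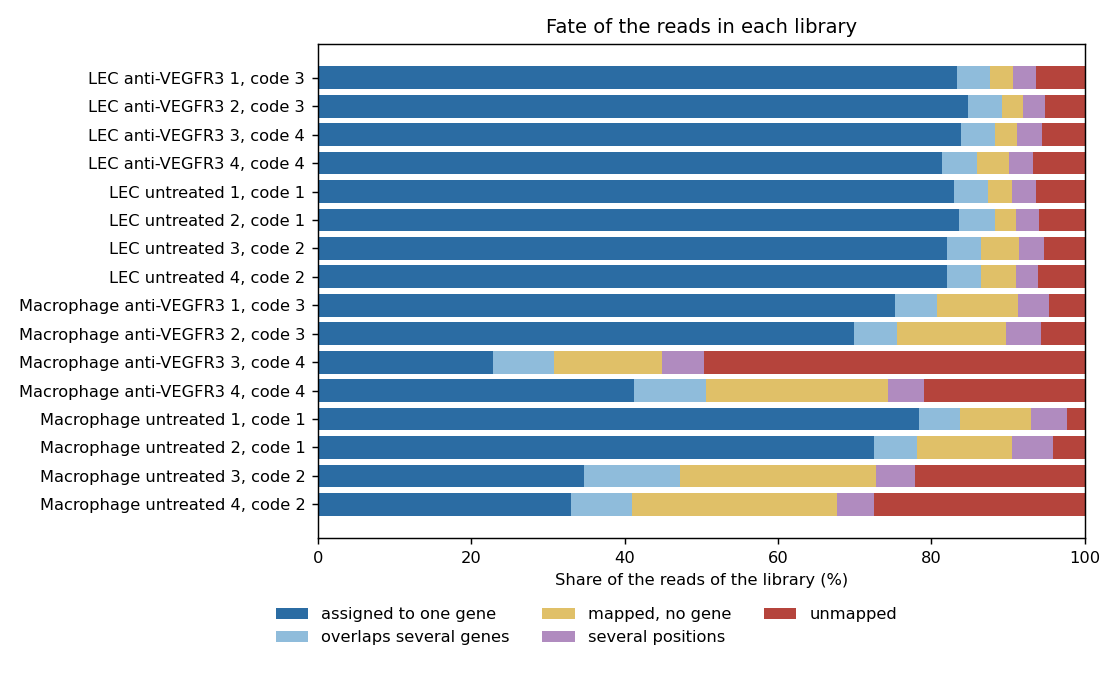
Share of reads (x axis, percent of the reads of a library) assigned to 1 gene, overlapping several genes, mapped outside genes, mapped to several positions or unmapped, as stacked bars for each of the 16 libraries with its sample code. Macrophage libraries coded 2 or 4 had 22.8% to 41.2% of reads in genes, against 69.9% to 78.3% in those coded 1 or 3 and 81.4% to 84.8% in LEC.

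Untreated LEC and untreated macrophages differed in a large part of the measured transcriptome. Of 14343 genes tested, 6443 (44.9%) were called, 2770 higher in LEC and 3673 higher in macrophages, at a fold change of at least 2. Large differences were called mostly on the macrophage side. At 8-fold or more, 325 genes were higher in LEC and 1642 in macrophages. At 32-fold or more the counts were 78 and 539. Detection was unequal, which could lower the counts on the LEC side. The upper limit for a gene without counts was 0.0631 to 0.0894 CPM in LEC libraries and 0.131 to 1.49 CPM in macrophage libraries. Whether this accounts for the imbalance was not tested, and large differences were not counted within code sets.

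On the macrophage side, ENSMUSG00000069792.5 was at 140 ± 32.5 CPM in macrophages and 0.245 ± 0.0867 CPM in LEC (SD, n = 4 each), a log2 fold change of -9.11 (SE 0.37) for LEC over macrophages with an edgeR quasi-likelihood BH-adjusted p of 5.37e-07. ENSMUSG00000009185.2 was at 106 ± 17.3 CPM in macrophages and 1.62 ± 0.187 CPM in LEC, a log2 fold change of -6.02 (SE 0.26) with the same adjusted p. On the LEC side, ENSMUSG00000034845.5 was at 200 ± 81.6 CPM in LEC and 3.21 ± 1.56 CPM in macrophages, a log2 fold change of 5.94 (SE 0.44, edgeR BH-adjusted p = 3.23e-06). ENSMUSG00000009097.9 was at 27.3 ± 13.2 CPM in LEC, with 4319 counts over the 4 libraries, and had 1 count in the 4 macrophage libraries together. The ratio of its normalised counts was 1200, with a 95% counting interval of 215 to 47409.

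The untreated macrophage libraries included 2 of each code set, so the comparison was repeated within codes, a choice made after the data were seen. Of 13618 genes tested both among libraries coded 1 or 3 and among those coded 2 or 4, with 2 libraries per cell type, 11290 (82.9%) differed in the same direction in both, where 50% is the value without any difference. Of these genes 5966 were called among codes 1 or 3 alone. Among codes 2 or 4, 5719 of them (95.9%) had the same direction and 4039 (67.7%) were also called. Of all genes tested in both, 45.7% were called among codes 2 or 4. Among libraries coded 2 or 4 alone, calls were nearly even in direction, 3417 higher in LEC and 3410 higher in macrophages, against 2829 and 4169 among those coded 1 or 3.

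**Figure D2:**
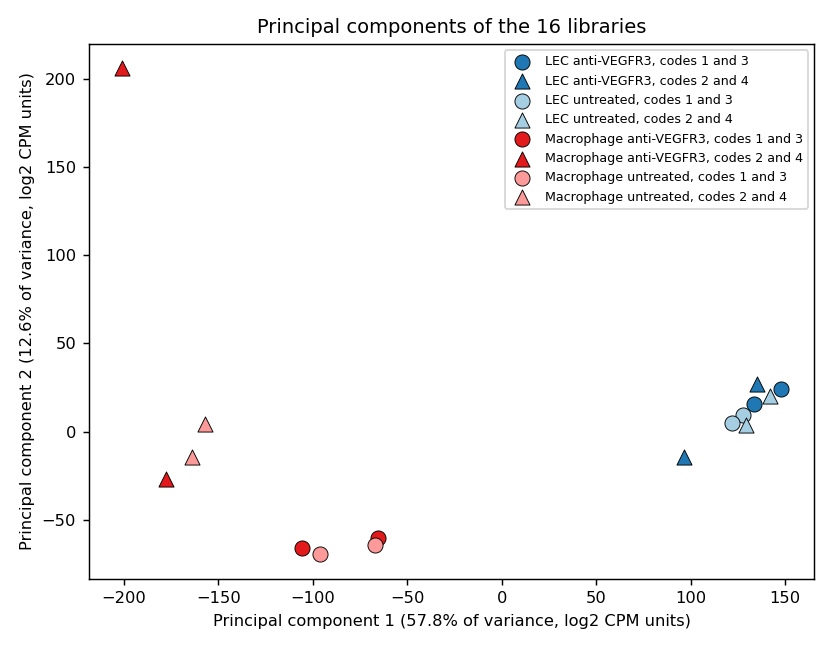
Principal components 1 (x axis, 57.8% of variance) and 2 (y axis, 12.6%) of log2 CPM of 16325 genes, with a point for each of the 16 libraries, coloured by cell type and treatment and shaped by sample code. LEC and macrophages lie apart on component 1, macrophage libraries part by code, and treated and untreated libraries intermingle, except that macrophage anti-VEGFR3 replicate 3, the library with 49.6% unmapped reads, stands alone at 206 on component 2.

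No gene passed BH adjustment for anti-VEGFR3 treatment of LEC. The edgeR quasi-likelihood test called 0 of 13931 genes and gave 143 (1.03%) an unadjusted p under 0.05, and the smallest BH-adjusted p was 0.9999. With 1 library left out the count at unadjusted p under 0.05 ran from 91 to 419, still with 0 calls. DESeq2 also called 0 (215 genes at unadjusted p under 0.05), as did limma voom (1085 genes). Every treated library was above every untreated one for 44 genes and below for 66, together 0.79% of genes, where chance alone gives 2.86%. The median absolute log2 fold change was 0.13 and the median SE 0.26.

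The data set limits on the size of a treatment effect in LEC, averaged over both code sets. The 95% interval of the fold change lay within 2-fold in either direction for 8807 genes (63.2%) and within 4-fold for 11629 genes (83.5%). For the other genes a larger change could not be excluded at this replication. These limits do not bound the effect within a code set, as the fold changes of the code sets shared a sign for only 29.3% of genes. The fit takes libraries of the same code as independent, although each treatment group holds only 2 codes. If libraries of a code share a source, these limits could be too narrow.

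Among the LEC genes with the smallest p, none of which passed, ENSMUSG00000064339.1 was the most abundant, at 294 ± 57.8 CPM untreated and 173 ± 52.7 CPM treated (SD, n = 4 each), a log2 fold change of -0.77 (SE 0.24). ENSMUSG00000002020.15 was at 8.85 ± 5.50 CPM untreated and 2.01 ± 1.13 CPM treated (log2 fold change -2.14, SE 0.62). ENSMUSG00000045394.8 was at 1.03 ± 0.655 CPM untreated and 13.9 ± 18.0 CPM treated (log2 fold change 3.74, SE 1.09, and 2.29 without LEC anti-VEGFR3 replicate 3). ENSMUSG00000026531.4 was at 0.241 ± 0.263 CPM untreated and 39.8 ± 73.3 CPM treated (log2 fold change 7.37, SE 2.16, 3.70 without the same library and 8.36 without LEC untreated replicate 2), where 1 of the 4 treated libraries was at 150 CPM and the others at 0.114 to 9.07 CPM. The edgeR BH-adjusted p of all 4 was 0.9999.

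Within code sets, with 2 libraries per group, edgeR called 0 LEC genes in either set. Among codes 1 or 3 it gave 2397 of 13994 genes an unadjusted p under 0.05 (smallest edgeR BH-adjusted p 0.0536). Among codes 2 or 4 it gave 1226 of 14598 (smallest 0.590). DESeq2 called 809 among libraries coded 1 or 3 (459 higher and 350 lower with treatment). Among those coded 2 or 4 it called 247 (146 higher and 101 lower). These fits were chosen after the data were seen. Each compares libraries of 1 code with those of another, so treatment and code cannot be told apart within it. Of the DESeq2 calls, 2 were higher with treatment in both sets, against 5.31 for independent lists, and 0 were lower in both, against 2.80. Genes called in both sets in opposite directions numbered 38 and 29, for those higher and those lower among codes 1 or 3, against 3.67 and 4.05 for independent lists.

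**Figure D3:**
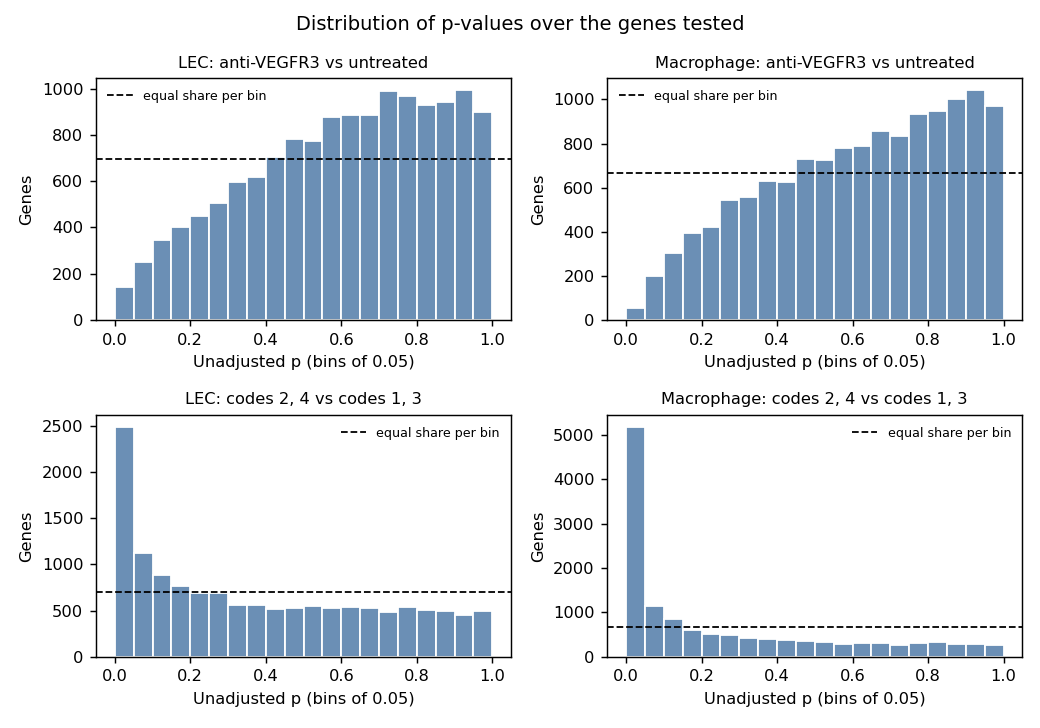
Number of genes (y axis) by unadjusted p (x axis, bins of width 0.05) from the edgeR quasi-likelihood test, for treatment and for sample code in LEC (13931 genes) and macrophages (13354 genes), with a dashed line at an equal share per bin. The treatment panels hold fewer genes than the line in the lowest bin (143 and 57), and the code panels more (2493 and 5183).

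In macrophages too, no gene passed BH adjustment between anti-VEGFR3 and untreated libraries. The edgeR quasi-likelihood test called 0 of 13354 genes and gave 57 (0.43%) an unadjusted p under 0.05, with a smallest BH-adjusted p of 0.9999. DESeq2 called 0 (146 genes at unadjusted p under 0.05) and limma voom 0 (519 genes). In the pairs of same-numbered libraries, a count added after the data were seen, the treated library was higher in all 4 for 763 genes and lower in all 4 for 730, together 11.2% of genes, where chance gives 12.5%. The median SE of the log2 fold change was 0.48.

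The limits on a treatment effect were wider in macrophages than in LEC: the 95% interval of the fold change lay within 2-fold for 3835 genes (28.7%) and within 4-fold for 9952 (74.5%) in the fit without a block. With the replicate number as a block the count of calls was again 0, and the interval lay within 2-fold for 6041 genes (45.2%) and within 4-fold for 10513 (78.7%). As in LEC, each treatment group holds only 2 codes, and the limits could be too narrow if libraries of a code share a source. The macrophage groups each hold 2 libraries with the lower gene totals and higher unmapped shares of codes 2 or 4. Within code sets edgeR called 0 genes in either, and DESeq2 called 7 among libraries coded 1 or 3 (2 higher and 5 lower with treatment) and 2 among those coded 2 or 4 (both lower).

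Of the macrophage genes with the smallest p, none of which passed, ENSMUSG00000056054.9 was at 6.13 ± 7.30 CPM untreated and 0.358 ± 0.239 CPM treated (SD, n = 4 each; log2 fold change -3.97, SE 0.97). ENSMUSG00000056071.12 was at 6.27 ± 7.89 CPM untreated and 0.510 ± 0.347 CPM treated (log2 fold change -3.54, SE 1.00). The untreated means of both rest largely on replicate 2, which was at 17.0 and 18.0 CPM. Without it the log2 fold change of the first was -2.66, and the second did not pass the filter on low counts. ENSMUSG00000051113.9 was at 0.375 ± 0.141 CPM untreated and 4.28 ± 5.55 CPM treated (log2 fold change 3.37, SE 1.12, and 1.94 without macrophage anti-VEGFR3 replicate 3), and ENSMUSG00000068744.12 at 3.45 ± 1.94 and 12.8 ± 13.1 CPM (log2 fold change 1.82, SE 0.70, and 0.80 without the same library). With the replicate block these 2 were at 1.96 and 1.43, and their change lay mainly among codes 2 or 4 (4.65 and 3.38) and less among codes 1 or 3 (0.61 and 0.12). The edgeR BH-adjusted p of all 4 was 0.9999.

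The treatment effect was then compared between the cell types. The edgeR quasi-likelihood test of the difference called 0 of 16325 genes, with 272 at an unadjusted p under 0.05. DESeq2 called 1 gene (413 at unadjusted p under 0.05) and limma voom 4 (1116), 1 with a treatment effect higher in LEC and 3 lower. The DESeq2 call was ENSMUSG00000018168.8. Over the 4 treated LEC libraries it had 0 counts, against 147 counts over the 4 untreated ones (0.988 ± 0.991 CPM, SD), and in macrophages it was at 2.31 ± 2.10 CPM treated and 2.01 ± 1.22 CPM untreated. Its adjusted p was 0.0362 with DESeq2 and ranged up to 1 over the settings tried, and it was not called by edgeR or voom.

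Of the other genes with the smallest p for this difference, ENSMUSG00000010064.15 was at 0.845 ± 0.357 CPM in treated and 0.321 ± 0.130 CPM in untreated LEC, and at 0.137 ± 0.200 CPM in treated and 2.33 ± 2.34 CPM in untreated macrophages (SD, n = 4 each). ENSMUSG00000017639.13 had 1 count in the treated LEC libraries together and 45 in the untreated ones, with 3.57 ± 4.95 CPM in treated and 1.78 ± 1.56 CPM in untreated macrophages. Its treated macrophage mean rests largely on replicate 3, at 10.98 CPM. The other treated macrophage libraries were at 0.948 to 1.21 CPM, below the untreated mean. ENSMUSG00000055373.8 had 60 counts in treated and 0 in untreated LEC, and 9 in treated and 18 in untreated macrophages. Its treated LEC level of 0.378 ± 0.548 CPM rests largely on 1 library, at 1.17 CPM. Across 12297 genes tested in both cell types, the treatment fold changes in LEC and macrophages had a Pearson r of 0.0853 and a Spearman rho of 0.121, a description across genes, which are not independent replicates.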

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

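Tests chosen only after their result was seen were the splits of the samples for both treatment comparisons and for the difference between them, and the test of LEC RNA in macrophage libraries; the comparisons between sample codes were themselves added once the library totals were known.

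A gap between 1 library and the other 3 of its group was tested in 88 groups of values and was wide in 11, where chance marks about 1 in 20 groups of normally distributed values, a rate that does not hold for low counts. The share of reads mapped outside genes was 4.27% in LEC anti-VEGFR3 replicate 4, against 2.76% to 2.92% in the others. ENSMUSG00000026531.4 was at 150 CPM in LEC anti-VEGFR3 replicate 3, against 0.114 to 9.07 CPM. ENSMUSG00000034845.5 was at 321 CPM in LEC untreated replicate 3, against 146 to 166 CPM. ENSMUSG00000017639.13 was at 0.0303 CPM (1 count) in LEC anti-VEGFR3 replicate 1, with 0 in the others, which makes the gap wide by construction, and at 10.98 CPM in macrophage anti-VEGFR3 replicate 3, against 0.948 to 1.21 CPM. In the same macrophage library ENSMUSG00000068744.12 was at 32.3 CPM, against 5.19 to 8.22 CPM, and ENSMUSG00000056054.9 at 0, against 0.463 to 0.503 CPM, although 3 counts in that library correspond to 0.618 CPM, so this 0 does not show a lower level. ENSMUSG00000056054.9 and ENSMUSG00000056071.12 were at 17.0 and 18.0 CPM in macrophage untreated replicate 2, against 1.65 to 3.25 and 1.39 to 3.35 CPM in the others. ENSMUSG00000009097.9 was at 0.0437 CPM (also 1 count) in macrophage untreated replicate 1, with 0 in the others, and ENSMUSG00000055373.8 at 0.376 CPM in macrophage anti-VEGFR3 replicate 1, against 0 to 0.0412 CPM, where 3 counts in replicates 3 and 4 correspond to 0.804 and 0.603 CPM, so a 0 there does not show a lower level.

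Other splits of the samples were run for each comparison. For LEC treatment the real split gave 0 calls, which all 35 splits must reach, so this count tests nothing; 31 of the 35 gave at least its 143 genes at unadjusted p under 0.05, and the highest other split, 113 calls, was that by sample code. For macrophage treatment the real split also gave 0 calls, 29 of 35 gave at least its 57 genes at that p, and the highest other, 3644 calls, was again the split by sample code, which points to a structure of the libraries apart from treatment. Of the splits, 8 part all 4 pairs of same-numbered macrophage libraries, whose pairing was not shown. The highest other among these also gave 0 calls, with 47 to 118 genes at unadjusted p under 0.05 against 57 for the real one. The code split keeps no such pair apart. With the code as a block, both treatment comparisons stayed at 0 calls. For the difference of treatment effects the real split gave 0 calls, which all 100 drawn splits must reach, 89 of them gave at least its 272 genes at unadjusted p under 0.05, and the highest other gave 3535 calls. For untreated LEC against macrophages, 1 of 35 splits, the real one, gave as many as 6443 calls and the highest other gave 0. This count cannot exclude chance, as 1 of 35 is the smallest share possible. Every other split also mixes the cell types within its groups, which widens their spread.

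Macrophage libraries coded 2 or 4 differed from those coded 1 or 3 in 3644 of 13354 genes (1909 higher and 1735 lower). Only 1 of 35 splits reached this count, the real one, with 0 for the highest other. This cannot exclude chance, as 1 of 35 is the smallest share possible. Every other split mixes the code sets within its groups, which widens their spread. The code sets were also compared only once the totals of these same libraries were known. The count ran from 2202 without macrophage untreated replicate 1 to 4831 without macrophage anti-VEGFR3 replicate 3. It was 2314 without macrophage anti-VEGFR3 replicate 1. Libraries were treated as independent, although same-numbered ones lie in the same code set, so any pairing would make the spread too small. Read depth as the whole cause is argued against by 3435 calls once every library was thinned to the smallest total, and a few dominant genes by 3207 calls without the 20 genes that held 50.3% of counts, at equal totals. RNA from LEC was checked over 3887 genes above 50 CPM in LEC, which were not chosen as specific to LEC. Their median level was 64.3% of that in LEC in libraries coded 1 or 3 and 39.6% in those coded 2 or 4. The difference of 24.7% need not be a share of LEC RNA. Of the 3887 genes, 15 stayed under 2% of their LEC level in each library coded 1 or 3. For these 15 genes this argues against a larger, evenly mixed share of LEC RNA. Other values went with LEC RNA in libraries coded 1 or 3. Across 12923 genes, fold changes of codes 2 or 4 over 1 or 3 and of untreated LEC over macrophages had Pearson r -0.543. Of 1711 genes called lower in codes 2 or 4, 733 were called higher in LEC, against 2439 of all 12923. Both comparisons use the untreated macrophage libraries, so they are not independent. A small or uneven share of LEC RNA stays open. A difference between batches, cell sources or RNA handling, and RNA from another cell type or organism in the libraries coded 2 or 4, stay open, as the labels do not state what the code means. The design names no group that parts these libraries, so no biological explanation was tested.

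In LEC the treatment fold changes among codes 1 or 3 and among codes 2 or 4 correlated negatively across 13931 genes (Pearson r -0.318, Spearman rho -0.477). They shared a sign in 29.3%. An edgeR interaction of treatment and code set called 0 genes (smallest BH-adjusted p 0.0921), with 3047 (21.9%) at unadjusted p under 0.05. Calls rose to 351 without LEC anti-VEGFR3 replicate 3 and to 628 without replicate 4. Of 100 assignments of the libraries only 1, the real one, gave 3047 genes at that p, though the highest other gave 2906. Unequal depth is argued against by 3031 such genes after thinning every library to the smallest total, and a single library as the whole cause by 1688 at the lowest, without LEC anti-VEGFR3 replicate 2. Each code occurs in only 1 treatment group, so this interaction is the same contrast as codes 1 or 4 against codes 2 or 3. A response that differs between the code sets therefore cannot be told apart from plain differences between codes. Library batches and exchanged treatment labels in one code set stay open too. The split of codes 1 or 4 against 2 or 3 gave 0 calls but 2494 genes at unadjusted p under 0.05. The labels as given had 143. In macrophages the same interaction gave 0 calls and 634 genes (4.75%), with 369 calls without anti-VEGFR3 replicate 4.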

How the results depend on the processing

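The sum of both strand columns, the fits on part of the codes, the comparisons between codes and the recovery in the blocked fit were chosen after the data were seen. Both treatment comparisons stayed at 0 calls under 13 of 15 alternatives each and with each library left out (0 to 0). The exceptions were DESeq2 with 2 libraries per group: in LEC 809 calls among codes 1 or 3 and 247 among codes 2 or 4, in macrophages 7 and 2. The edgeR fits on the same libraries called 0, and why the tools differ was not tested. The difference of treatment effects stayed at 0 under 9 of 11 alternatives and with each library left out (0 to 0), and gave 1 call with DESeq2 and 4 with limma voom; the cause was not tested. Untreated LEC against macrophages gave 6155 to 7003 calls under 10 of 11 alternatives and 6310 to 7020 with a library left out; without a filter on low counts it gave 9737 of 31737 genes, as more genes were tested. LEC codes 2 or 4 against 1 or 3 gave 113 to 152 calls under 4 of 8 alternatives, but 1212 with DESeq2, 364 with limma voom, 189 with one strand column, 60 with treatment as a covariate, and 8 (without LEC anti-VEGFR3 replicate 1) to 434 (without LEC untreated replicate 4) with a library left out; the cause was not tested. The same comparison in macrophages gave 3315 to 4608 under 7 of 8, 9102 of 32329 genes without the filter, and 2202 to 4831 with a library left out. With the replicate block, both treatment comparisons and their difference stayed at 0 calls and the cell types differed in 6313 genes, so it changed no call by over 1.5 times; with the shared code as a block the cell types differed in 6383 genes and the difference of treatment effects gave 0 calls; in LEC, where the numbers were not taken to pair the libraries, replicates 3 and 4 correlated best with their own number and replicates 1 and 2 did not. Of 348 values of the 16 identifiers under other settings, 342 kept their side of the threshold, 6 passed it and 0 changed direction. Of the 6, 5 came from DESeq2 with 2 libraries per group and the other was ENSMUSG00000018168.8. Settings in which an identifier failed the filter or had no adjusted p are not among these values. The identifiers were picked by smallest p in the same libraries, so a kept direction was largely fixed in advance and is no independent support. The largest move of a median log2 fold change under DESeq2 size factors was 0.04, in the macrophage comparison between codes. Set tests of the gene lists and the naming of genes by symbol, with their alternatives, were not run, as no identifier matched a symbol. Without a block 17% of simulated 4-fold changes were recovered in the macrophage treatment comparison against 58% in LEC, and the same macrophage libraries gave 65% with the replicate block and 72% in the comparison between codes, so depth alone did not set this limit.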

Other observations

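The tests in this part were added after the data were seen, with the expected outcome of the splits by sample code written down before they were run. Exact permutation tests are two-sided.

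Cell-cycle marker pairs, gene pairs whose order of expression marks a phase, could be matched in full: 12052 pairs for G1, 6459 for S and 9981 for G2/M, from the mouse list of scran. The score is the percentage of pairs in which the phase marker was higher. Untreated LEC had higher scores than untreated macrophages for S (48.5% ± 0.584 against 40.9% ± 1.47, SD, n = 4 each) and for G2/M (54.1% ± 1.45 against 49.8% ± 2.42), and a lower score for G1 (40.1% ± 2.43 against 48.8% ± 4.63). Each of these differences had an exact permutation p of 0.0286, the smallest possible, and a BH-adjusted p of 0.0536 over 15 tests, so none passed a threshold of 0.05 after adjustment. With anti-VEGFR3 none of the 6 tests passed: the smallest exact permutation p was 0.314, for S in LEC (47.9% ± 0.916 treated and 48.5% ± 0.584 untreated, n = 4 each), and the largest 0.886, for G2/M in macrophages (49.9% ± 1.91 and 49.8% ± 2.42, n = 4 each). Between code sets 5 of 6 scores reached the smallest possible p, with G1 in macrophages at 52.96% ± 1.43 in codes 2 or 4 and 45.5% ± 1.37 in codes 1 or 3 (exact permutation p = 0.0286, BH-adjusted p = 0.0536), and S in LEC did not (47.8% ± 0.937 against 48.7% ± 0.212, exact permutation p = 0.114).

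LEC libraries coded 2 or 4 differed from those coded 1 or 3 in 113 of 13931 genes by the edgeR quasi-likelihood test, 106 of them higher in codes 2 or 4 and 7 lower, while DESeq2 called 879 higher and 333 lower. Of 35 splits only 1, the real one, gave 113 calls, and the highest other gave 0, though 8 calls were left without LEC anti-VEGFR3 replicate 1. This count of splits cannot exclude chance, as 1 of 35 is the smallest share possible and every other split mixes the code sets. By genes at unadjusted p under 0.05, 2 of the 35 splits reached the 2493 of the real one, the other with 2494.

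ENSMUSG00000098178.1 had 0 counts in the column that ignores strand in all 16 libraries, yet held 18.3% ± 4.48 (SD, n = 4) of the summed strand columns in macrophage libraries coded 2 or 4, 0.888% ± 0.348 in those coded 1 or 3 and 0.0292% ± 0.0101 in LEC. Reads over genes on both strands count as overlapping several genes in the first column and as single genes in the strand columns, so this gene enters none of the comparisons above except under the strand columns.

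The 2 genes that DESeq2 called lower with anti-VEGFR3 in macrophage libraries coded 2 or 4 were ENSMUSG00000075015.3 (log2 fold change -2.50) and ENSMUSG00000075014.1 (log2 fold change -2.39), each with a DESeq2 adjusted p of 0.0164. They are named as the calls of this fit, outside the rule for identifiers. DESeq2 also called 7 genes among macrophage libraries coded 1 or 3, 2 higher and 5 lower with treatment. The smallest DESeq2 adjusted p there was 1.69e-10, for ENSMUSG00000029379.10 (log2 fold change 2.78). The edgeR fits called 0 genes in either code set. Each fit has 2 libraries per group, and treatment cannot be told apart from code within it.

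Treated LEC libraries lay farther from each other than untreated ones, with a mean root-mean-square log2 CPM distance between libraries of 1.20 against 0.793, but the difference did not pass an exact permutation test (p = 0.0857, 4 libraries each), and without LEC anti-VEGFR3 replicate 3 the distances were 1.04 and 0.793. In macrophages the distances were 1.48 and 1.23 (exact permutation p = 0.771), and with a library left out treated minus untreated ran from -0.22 (without anti-VEGFR3 replicate 3, at 1.00 and 1.23) to 0.52 (without anti-VEGFR3 replicate 2).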
